A study of Drosophila melanogaster with 2 samples.

How the data were processed

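Chromatin immunoprecipitation was done with an antibody against GFP on whole embryos of a line that carries sug fused to eGFP, aged 8 to 24 hours, with fragments of 200 to 800 bp per the labels, in 2 biological replicates. Per the text files deposited with the peak lists, the assembly was dm6, peaks were called by the authors on the alignments of each replicate together with a control, and the thresholded set was derived from both replicate lists and a list called on the pooled reads. The aligner, the peak caller and their versions are not given in the sources used here, and the control was not analysed here.

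The lists deposited by the authors give for each summit a signal value, which is a score scaled within its own list, and a −log10 q. Signal scores were used to rank, filter and compare summits within a peak list and never between peak lists. The −log10 q that the authors deposited is at its highest value, 4.38, in all 9342 rows of the IDR set, so it ranks nothing there and was not used in a test. The replicate and pooled lists each hold exactly 30000 rows, so they were capped. All 9342 rows of the IDR set are rows of the pooled list, and they are its 9342 highest in signal. Intervals can hold several summits: 1547 IDR rows share an interval with another. In 2 IDR rows the summit offset lay past the interval and was set to its end. No read counts or depths were given in the sources used here, so the depth per replicate is unknown and no precision is derived from it.

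Coordinates are 1-based on dm6. Genes, exons and TSSs came from the Ensembl annotation of the same assembly (release 115) and sequence from the RefSeq copy of that assembly, and all summits lay within its chromosome lengths. Transposable element annotations were left out. The background held 18277 genes, of which 13968 are protein-coding, and 5485 of these (39.3%) had an IDR summit within 1 kb of a TSS. Summits were placed in the first that applied of promoter (within 1 kb of a TSS), 5 prime UTR, 3 prime UTR, coding exon, other exon, intron and intergenic.

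Groups, tests, gene lists, words and most alternatives were fixed before the data were examined. Agreement between replicates was the share of the 9342 highest summits of replicate 1, less 21 mitochondrial ones, with one of replicate 2 within 100 bp, against 1000 uniform relocations. Classes were tested against 10000 relocations of every summit on its own arm, two-sided. The difference in promoter share between the 1869 summits with the highest and the 1868 with the lowest signal was tested with 10000 permutations. Gene lists were compared with 10000 random lists of the same biotype matched on quartile of gene length and on number of TSSs (tRNA genes with other non-coding genes). Genes were drawn singly, so neighbouring members that share a summit count separately. For lists with many neighbouring members the p can therefore be too small. The words were tested by their presence within 100 bp of the summit against a window of the same length centred 500 bp to the left, with an exact McNemar test, and folds are over the mean of both flanks. Fisher's exact test was used for promoter against distal summits, and the words were tested at promoter summits alone, both chosen after the data were seen. The numbers of summits per arm have intervals from 10000 block bootstrap draws over 100 kb blocks. Benjamini-Hochberg adjustment was applied over classes, lists or words, with a threshold of 0.05. Peaks are not independent replicates, so these tests describe where the peaks of this set lie and not the spread between embryo collections.

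Named genes are those of the 15 highest peaks (only the highest within 1 kb, named by the nearest TSS), the 6 protein-coding genes with the most summits, sug, 16 genes fixed for their roles in sugar and lipid metabolism or in the hedgehog and GLIS-related pathways, and up to 3 genes of each fixed list with the strongest promoter peak. For each promoter the highest IDR summit within 1 kb is given.

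The tests were run on simulated data first. Uniform positions gave a promoter p under 0.05 in 1 of 50 runs, and implanted promoter peaks were recovered at 1.00 of the known share. Of 200 random gene lists 5 had p under 0.05, and of 100 lists with 18 of 20 genes bound all 100 did. Bound genes were drawn there at random, without shared summits, clustered families or dependence on gene length. These runs therefore do not show how the list test behaves for lists of neighbouring genes. The motif test found 0 of 12 words at uniform positions and all 186 windows with an implanted word.

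Alternatives were the 4671 IDR summits with the higher signal, the highest summits of each replicate list alone, other promoter windows, a window of 100 kb around sug, other overlaps, other motif windows and controls, unmatched random lists and binding anywhere in the gene. A stricter IDR score could not be applied because that column is 0 in every row. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.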

Results

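The genome-wide binding of sugarbabe (sug), a zinc finger transcription factor related to the GLIS family and known for its induction by dietary sugar, was measured by ChIP-seq in Drosophila melanogaster embryos. The embryos came from a transgenic line that expresses sug fused to eGFP, were of mixed sex, were collected whole from 8 to 24 hours, and were precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, and a group without the tagged protein was not analysed here. Each replicate had a list of 30000 summits, the pooled reads had a list of 30000, and the set kept by the authors' irreproducible discovery rate (IDR) threshold held 9342 summits in 8530 distinct intervals on dm6. No read counts were given in the sources used here, so the depth is unknown. Signal values per summit are the authors' own and were used only within a list.

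Binding sites were shared between the replicates far more often than uniformly relocated summits would be. The share itself describes how well the same sites were recovered from separate embryo collections. Relocation ignored the preference for promoters, so its p does not separate sites of the tagged factor from a common recovery of promoters. Of the 9342 highest summits of replicate 1, 21 were mitochondrial and were left out, and 69.6% of the other 9321 had a summit of the 9342 highest of replicate 2 within 100 bp, against a mean of 1.40% for relocated summits (permutation p = 0.000999, the smallest that 1000 relocations can give). The summit with the highest signal in the IDR set, inside sug, ranked 1 in replicate 1 and 3 in replicate 2. The summit next in signal, at Atg2, an autophagy gene, ranked 6 and 1. Among the 9342 IDR summits, 8419 (90.1%) had a summit within 100 bp in both replicate lists and 24 had one in neither. The set was derived by the authors from these lists and the pooled list, and equals the 9342 highest summits of the pooled list. This share is therefore not an independent measure of agreement. The Spearman rho of signal between replicates across those 8419 summits was 0.689, a description across peaks, which are not independent replicates. Summits of the replicate 1 set that had no partner in replicate 2 lay within 1 kb of a transcription start site (TSS) in 67.8% of 2834 cases (95% Wilson interval 66.1 to 69.5%), and those with a partner in 64.8% of 6487 (63.6 to 65.9%). In replicate 2 the same shares were 62.2% of 2854 unpaired summits (60.4 to 64.0%) and 64.8% of 6488 paired ones (63.6 to 65.9%).

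The summit with the highest signal of the IDR set lay in the sug gene itself, and 3 of the 6 highest summits were in that gene. The gene (FBgn0033782) spans 12924567 to 12930644 on the plus strand of 2R, and 5 IDR summits fell inside it, all in 1 interval from 12924112 to 12929246. The summit at 12928467, in an intron and 393 bp from the nearest TSS, had a signal of 24384, which is 57.5 times the median of the IDR set and the highest of all 9342. The intronic summits at 12925590, 12927338 and 12926393 had signals of 17485, 15499 and 6694 and ranked 4, 6 and 42. A further summit at 12924642, in the 5 prime UTR, had a signal of 2722 and ranked 205. Of the 5 summits, 4 were intronic and 0 lay in a coding exon. The replicates gave these 5 summits ranks from 1 to 121 in replicate 1 and from 3 to 778 in replicate 2. Within 20 kb of the gene there were 6 more IDR summits, with signals from 252 to 2446 and a median signal percentile of 70.4. The total of 11 summits within 20 kb placed sug at the 88.1th percentile of the 3750 genes of the arm, whose median was 5 summits. That percentile was 98.6 when only the 4671 IDR summits with the higher signal were counted, among them the 5 inside the gene, and 92.8 within 100 kb, where there were 37 summits against a median of 20.

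**Figure D1:**
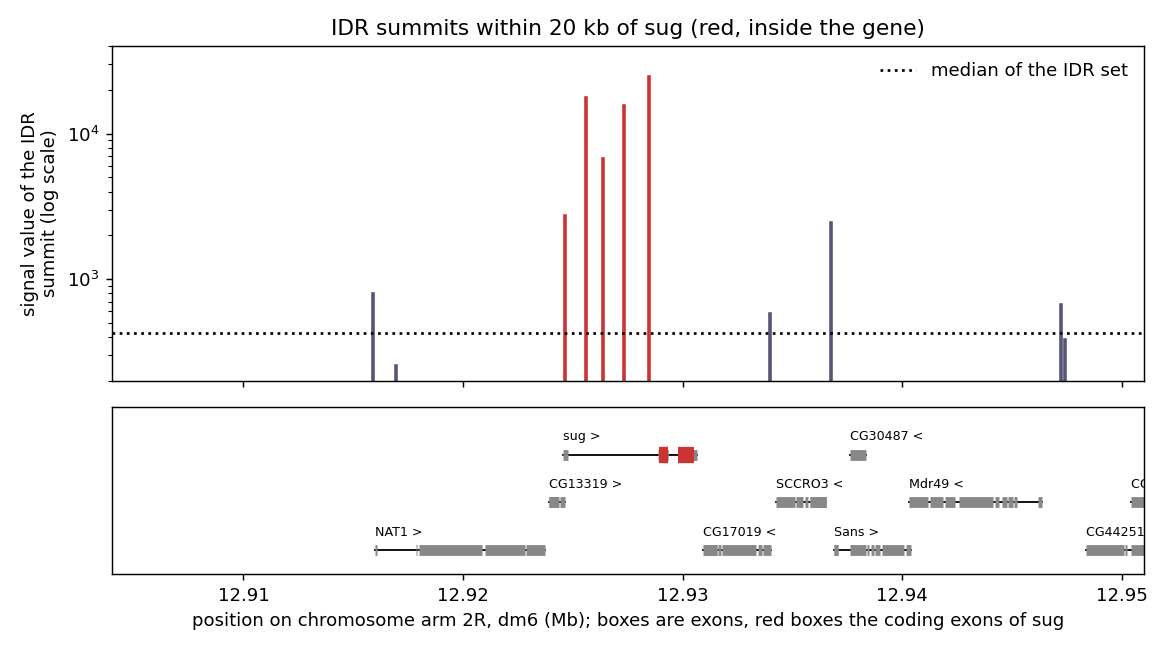
IDR summits within 20 kb of sug on 2R (x axis, position in Mb on dm6). Upper panel, each line is 1 summit and its height the authors' signal value on a log axis; the dotted line is the median of the IDR set (424). Lower panel, protein-coding genes with exons as boxes. The 5 red summits inside sug reach 2722 to 24384 and lie outside its coding exons, while the 6 others stay between 252 and 2446.

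Outside sug, the highest peaks included those at Hacl, Aldh7A1, Got2 and P5CDh1. The 15 highest peaks, spaced by more than 1 kb, included 3 in sug. The peak at Hacl (2R, 20244666 to 20245892), named for 2-hydroxyacyl-CoA lyase, had a signal of 16026 with its summit 63 bp from the TSS, and ranked 11 and 2 in the replicates. Aldh7A1, an aldehyde dehydrogenase (3L, 19268372 to 19269245), had a signal of 13673 at 83 bp from its TSS. Got2, an aspartate aminotransferase (2L, 1985989 to 1987294), had 12076 at 505 bp, in an intron. P5CDh1, an enzyme of proline breakdown (3L, 21839549 to 21840759), had 10237 at 210 bp, also in an intron. Atg2 (3L, 2773743 to 2774741) had 20013 at 67 bp, upstream of the gene body in intergenic sequence. Peaks at CG9467 (3R, summit 9801097), CG5793 (3R, summit 21127796) and CG1628 (X, summit 10602422) had signals of 12384, 11213 and 10287, all within 292 bp of a TSS. The remaining peaks were nearest to the TSS of a non-coding gene or lay more than 1 kb from a TSS. An intergenic summit at 13579839 on 2R, 1803 bp from the TSS of lncRNA:CR44366, had a signal of 17843, and 1 at 13396189 on X, in an exon of lncRNA:CR44621, had 14537. An intronic summit at 23210953 on 3R was 3604 bp from a TSS of cnc, the Nrf2-type stress regulator, with 11170. Another at 484681 on 2L was 4993 bp from the TSS of cbt (cabut, a zinc finger factor) and within the span of ush, with 10749. None of these 15 ranked below 35 in either replicate.

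Promoters carried most of the binding. Of the 9342 IDR summits, 6054 (64.8%, 95% Wilson interval 63.8 to 65.8%) lay within 1 kb of an annotated TSS, against 23.7% for summits relocated on their own arm, a 2.73-fold excess. Summits were fewer than relocated ones in introns (26.3% against 36.1%), intergenic sequence (6.24% against 25.2%), 3 prime UTRs (1.15% against 4.20%) and coding exons (0.546% against 9.93%). Each of these 5 differences had an adjusted p of 0.00014 (two-sided permutation test, the smallest that 10000 relocations can give before adjustment is 1e-04). Summits in 5 prime UTRs outside promoters (0.428% against 0.445%, adjusted p = 0.818) and in other exons (0.514% against 0.475%, adjusted p = 0.688) did not pass the permutation test. Each summit counts in 1 class and promoters come first, so the promoter excess by itself lowers the shares of the other classes. Their p therefore does not test avoidance or preference among summits outside promoters. Of the deficits, that in introns was the smallest (0.729-fold, against 0.273-fold in 3 prime UTRs, 0.248-fold in intergenic sequence and 0.0550-fold in coding exons). With relocation within 50 kb, an alternative chosen after the data were seen, the promoter share stood against 32.7% (1.98-fold) and the intergenic share against 12.9% (0.482-fold), both with a permutation adjusted p of 0.00014. The median distance to the nearest TSS was 370 bp, and 40.5% of summits lay within 200 bp of one. Of the promoter summits, 39.8% were within 1 kb of a TSS of more than 1 gene, so those peaks name a locus and not a single gene.

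**Figure D2:**
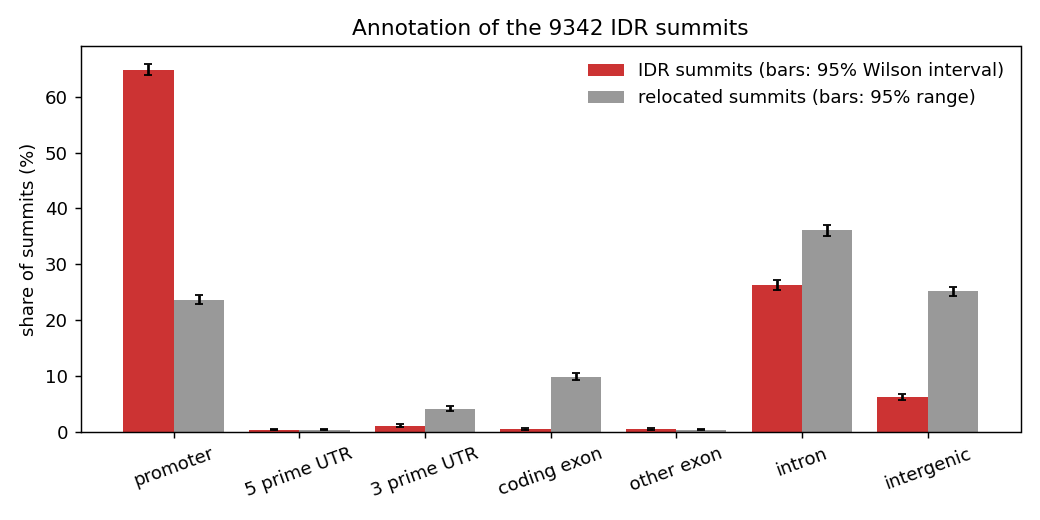
Share of the 9342 IDR summits in each annotation class (y axis, percent; red bars with 95% Wilson intervals) beside the mean of 10000 relocations (grey bars with their 95% range). Promoters hold 64.8% of summits against 23.7%, and coding exons 0.546% against 9.93%.

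Stronger peaks lay at promoters more often. Of the 1869 IDR summits with the highest signal, 69.3% were within 1 kb of a TSS (95% Wilson interval 67.2 to 71.4%), and of the 1868 with the lowest signal 60.4% (58.2 to 62.6%). The difference of 8.90 percentage points had a permutation p of 0.0001, the smallest that 10000 permutations can give. The 3 groups of that size between them had 64.6%, 65.2% and 64.5%. Within the 4671 higher-signal summits alone, the difference between the outer groups was 2.60 percentage points (permutation p = 0.23). It was 13.3 points in the highest summits of replicate 2 alone (permutation p = 0.0001) and 4.52 points in those of replicate 1 alone (permutation p = 0.0038).

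The small chromosome 4 carried few peaks, and the number on the X was near that given by its length. Chromosome 4 had 41 IDR summits, or 30.8 per megabase, which was 0.452 of the number its length gives (95% block bootstrap interval 0.272 to 0.641). The X had 1542 summits, or 65.7 per megabase, at 0.964 of that number (0.866 to 1.07). The arms 2L, 2R, 3L and 3R had 71.7, 75.2, 70.3 and 68.8 summits per megabase, with intervals that all include 1. No IDR summit lay on Y, and the lists contained no Y peaks at all. In the higher-signal summits alone chromosome 4 stood at 0.220 and the X at 0.875, both with intervals below 1.

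Genes of lipid synthesis were bound at their promoters more often than matched genes. In the list for fatty acid and lipid synthesis and storage, 17 of 19 genes (89.5%) had an IDR summit within 1 kb of a TSS, against 10.7 in random lists matched on gene length and number of TSSs (1.59-fold, permutation adjusted p = 0.00771 over 18 lists). AcCoAS, the acetyl-CoA synthetase, had the strongest promoter peak of the list, with a signal of 3014 at 199 bp from its TSS, ranking 136 in replicate 1 and 259 in replicate 2. Gpdh1, glycerol-3-phosphate dehydrogenase, and Lpin, the phosphatidate phosphatase lipin, followed with 2157 and 1819. ATPCL, the ATP citrate lyase, had 1476, with its summit 573 bp from the TSS, and SREBP, the lipogenic transcription factor, had 1105. The promoter peaks of ACC, the acetyl-CoA carboxylase, and of FASN1, a fatty acid synthase, had signals of 609.5 and 535.4, near the 69.8th and 63.5th percentiles of the IDR set. Desat1, a fatty acid desaturase, had 3 promoter summits, the highest at 287.8 with no replicate 1 summit within 100 bp.

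Lists of genes of sugar use were not bound more often than matched genes at the threshold. In the glycolysis list 11 of 13 genes were bound against 7.83 in matched lists (1.41-fold, permutation adjusted p = 0.150). Gapdh2 had a signal of 5833 (rank 52 of the IDR set), Eno 4035 (rank 99) and Hex-A 3263 (rank 150). Of the sugar-responsive regulators 9 of 12 were bound against 5.72 (1.57-fold, permutation adjusted p = 0.122), a list that includes sug itself. That list passed in 6 of the alternative settings, with adjusted p from 0.0113 to 0.049, so its call depends on the setting. Promoter summits of cbt, daw (an activin-type ligand) and Mondo (the sugar-sensing factor) had signals of 1827, 1539 and 1008, and bigmax, the Mondo partner, had 877.9 with no replicate 2 summit within 100 bp. Klf15 had no IDR summit at its promoter or in its body. Of the genes for carbohydrate digestion, transport and trehalose, 12 of 23 were bound against 9.20 (1.30-fold, permutation adjusted p = 0.435). Mal-A3 and Mal-A4, maltases transcribed away from each other, shared a peak with a signal of 2402, and Glut1, a glucose transporter gene, had 1791. Amy-p, the amylase gene, and tobi, a glucosidase gene, had 1235 and 1145, the latter with no replicate 1 summit within 100 bp. In the insulin and TOR list 11 of 22 genes were bound against 9.22 (permutation adjusted p = 0.624), led by Pi3K92E at 928.7, InR at 927.3 and Thor at 725.7.

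Ribosomal protein genes, fixed as a control for active housekeeping promoters, were bound more often than their matched genes. So were tRNA genes, fixed as a control for RNA polymerase III genes. Of 92 cytoplasmic ribosomal protein genes, 81 (88.0%) had a promoter summit against 37.2 in matched lists (2.17-fold, permutation adjusted p = 0.00045). RpL34b, RpS27 and RpL32 had the strongest peaks, with signals of 2386, 2385 and 1913. Of 290 tRNA genes, 83 (28.6%) were bound against 59.3 of other non-coding genes (1.40-fold, permutation adjusted p = 0.00045). Neighbouring genes that share a summit were counted separately, so this p can be too small. The tRNA call did not hold in the highest summits of replicate 2 alone (1.18-fold, permutation adjusted p = 0.0826), in the 4671 higher-signal summits (1.13-fold, permutation adjusted p = 0.492) or over the gene body (1.13-fold, permutation adjusted p = 0.421). Of 14 heat shock genes, 7 were bound against 5.45 (permutation adjusted p = 0.567), led by Hsp83 at 1390, Hsp27 at 1045 and Hsp68 at 607.3.

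Developmental patterning, neural, muscle and sensory genes were bound less often than matched genes. In the Hox and segmentation list 1 of 20 genes was bound, the pair-rule gene hairy (hry, signal 2704), against 9.94 in matched lists (0.101-fold, permutation adjusted p = 0.00045). In the highest summits of replicate 2 alone the fold for that list was 0.489 (permutation adjusted p = 0.0442), and it was 0.274 with a promoter of 2 kb and 0.367 over the gene body. Of 119 odorant and gustatory receptor genes 4 were bound against 42.3 (0.0946-fold, permutation adjusted p = 0.00045), with Or88a, Or9a and Gr63a at 631.2, 573.7 and 380.8. Among the neuron and glia genes 3 of 20 were bound against 10.9 (0.275-fold, permutation adjusted p = 0.00108). They were elav, a neuronal RNA-binding protein, with a signal of 3634, and Appl and fne, with 264.3 and 257.9. In the epidermis and trachea list 2 of 14 genes were bound against 7.17 (0.279-fold, permutation adjusted p = 0.009), namely trh, a tracheal regulator, at 1128 and crb, the polarity gene crumbs, at 519.3. Of the somatic muscle genes 6 of 24 were bound against 13.9 (0.432-fold, permutation adjusted p = 0.0036), led by Tm1 (tropomyosin) at 2044, sls at 1222 and mbc at 1090. The muscle regulator lmd, a GLIS-related factor, had no IDR summit. Calls for epidermis and trachea and for muscle did not hold among the 4671 higher-signal summits (permutation adjusted p = 0.279 each), and the former also did not hold in the highest summits of replicate 2 alone (0.407-fold, permutation adjusted p = 0.0502) or with a promoter of 2 kb (0.508-fold, permutation adjusted p = 0.0928). Against random lists without matching, those calls and the one for neurons and glia did not hold (permutation adjusted p from 0.076 to 0.382).

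Lists for fat body, gut, blood, germline and the hedgehog pathway did not pass the test. These lists have 9 to 13 genes, and for the haemocyte list the 95% range of matched lists ran from 22.2 to 88.9% bound. In the fat body list 7 of 13 genes were bound against 7.00 (permutation adjusted p = 1), with srp, a GATA factor, at 1239, Col4a1, a collagen, at 1158 and Mtp at 709.8. Gut and Malpighian tubule regulators had 5 of 12 against 5.93 (permutation adjusted p = 0.859), with GATAe at 1357, fkh at 685.0 and nub at 495.9. Haemocyte genes had 3 of 9 against 4.90 (permutation adjusted p = 0.435), with crq at 2019, ush at 521.9 and Ance at 328.2. Germline genes had 4 of 9 against 4.33 (permutation adjusted p = 1), with nanos at 2304, piwi at 467.6 and vas at 418.4. In the hedgehog pathway 6 of 12 genes were bound against 5.29 (permutation adjusted p = 0.859). There rdx, which encodes a ubiquitin ligase adaptor, had 2693, the GLI-type factor ci 641.0 and Su(fu) 375.2. The receptor gene ptc had 368.2.

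**Figure D3:**
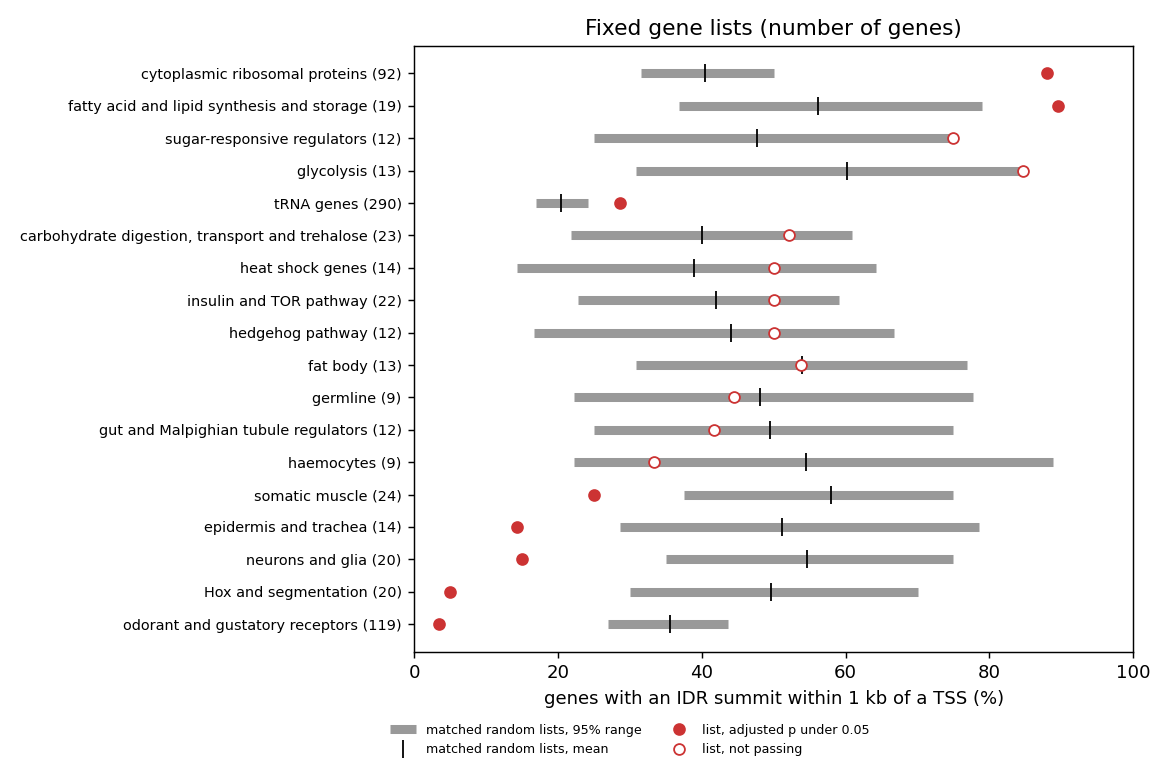
Share of genes in each of 18 fixed lists with an IDR summit within 1 kb of a TSS (x axis, percent; circles, filled where the adjusted p is under 0.05) beside 10000 matched random lists (grey bars, 95% ranges; ticks, means). Lipid synthesis and ribosomal protein genes lie near 89.5% and 88.0%, and odorant and gustatory receptors at 3.36%.

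Words known from promoter factors, GATA factors and GLIS proteins were concentrated at the summits. The GLIS-type word GACCCCCC occurred within 100 bp of 68 IDR summits (0.728%, 95% Wilson interval 0.575 to 0.922%), and was found in 0.0856% of the flanks centred 500 bp away (exact McNemar test, adjusted p = 1.03e-14). Its fold over flanks was 17.0 within 50 bp of the summit and 2.35 within 200 bp, the latter over flanks 1 kb away. In bins of 50 bp the word occurred 29 times at the summit, 1 time 500 bp to the left and 2 times 500 bp to the right. It occurred 9 times 900 bp to the left, so the fold depends on where the flank lies. The DRE word TATCGATA, of the promoter factor DREF, was found at 351 summits (3.76%, 6.05-fold, exact adjusted p = 2.02e-50). The M1BP word GGTCACACT, of another promoter factor, was found at 194 (2.08%, 6.93-fold, exact adjusted p = 7.31e-34). The GATA word AGATAAG was the most frequent of these 4, at 624 summits (6.68%, 2.17-fold, exact adjusted p = 2.51e-29). Smaller excesses passed for the E-box (1.26-fold, exact adjusted p = 0.000399), the GAGA word (1.27-fold, adjusted p = 0.00446) and the CA repeat (1.19-fold, adjusted p = 0.00208). These 3 did not pass in replicate 2 alone, and the GAGA word stood at 0.932-fold within 50 bp of the summit. The word of Zelda, an early embryonic activator, was less frequent at summits than in flanks (0.739% against 1.45%, exact adjusted p = 9.06e-05). The GLI-type word GACCACCC (1.62-fold, exact adjusted p = 0.124) and the words of Mef2 (1.22-fold, adjusted p = 0.132), AP-1 (1.19-fold, adjusted p = 0.117) and Grainy head (1.00-fold, adjusted p = 0.804) did not pass.

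Promoter words and GATA words were spread differently over promoter and distal peaks. DRE occurred at 5.57% of the 6054 promoter summits and 0.426% of the 3288 distal ones (Fisher's exact test, adjusted p = 6.68e-46), and the M1BP word at 3.15% and 0.0912% (adjusted p = 1.61e-31). The GATA word went the other way, at 5.34% of promoter summits and 9.15% of distal ones (exact adjusted p = 2.13e-11). The GLIS word, at 0.595% and 0.973%, did not pass (exact adjusted p = 0.101). Against their own flanks, the Mef2 word passed at promoter summits (1.78-fold, exact adjusted p = 0.00241) and not at distal ones (0.656-fold, adjusted p = 0.322), while its shares at the 2 kinds of summit, 0.942% and 0.639%, did not pass (Fisher's exact test, adjusted p = 0.203). The CA repeat (1.08-fold, exact adjusted p = 0.643) and the E-box (1.18-fold, adjusted p = 0.0675) did not pass at promoter summits. Among all 8192 words of 7 bases, 841 were more frequent at summits than in the left flank and 1211 less frequent at an adjusted p under 0.05. The word CTTATCA, a GATA site read on the other strand, had the lowest p, at 12.5% of summits against 4.13% of flanks (3.04-fold). Of the 50 enriched words with the lowest p, 17 contained GATAA on either strand, 9 others CGATA, 10 a run of C of 5 or more and 2 GTCAC. Words that contain both GATAA and CGATA, such as CGATAAG and TCGATAA, were counted under GATAA only, so more words hold CGATA than that count gives.

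**Figure D4:**
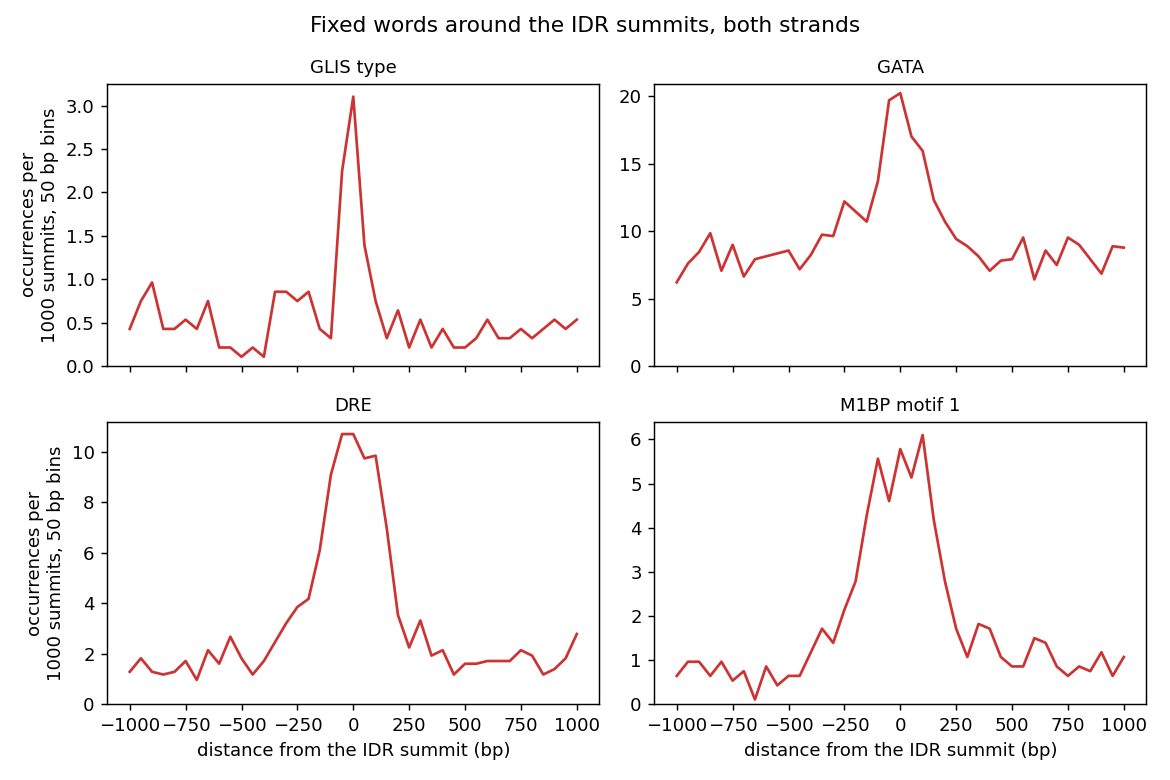
Occurrences of 4 fixed words on either strand around the 9342 IDR summits (x axis, distance in bp; y axis, occurrences per 1000 summits in bins of 50 bp, each panel with its own scale). Each word peaks near the summit, where the GLIS type is found within 100 bp of 0.728% of summits and the GATA word of 6.68%.

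Genes with the most IDR summits were long. Eip75B, an ecdysone-induced nuclear receptor gene (3L, 17950953 to 18064696), had 29 IDR summits from 1 kb upstream to its end, over 113.7 kb. The growth regulator gene bun had 26, shn, a zinc finger gene of the Dpp pathway, had 24, tara had 23, CG1677 had 22 and Pdp1, a clock-linked transcription factor gene, had 21. The gene ush also had 21 and tied with Pdp1, but is not among the 6 named. Genes of 5 kb or more were also ranked by these summits per kb of gene length. The length left out the 1 kb upstream in which summits were counted, which raises the values of shorter genes most. None of these 6 stayed among the first 6, which were led by Cdk4 (1.17 per kb), Drat (1.17 per kb) and Pgk (1.13 per kb).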

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

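Of the tests below, those on coding exons and on the signal of summits around sug, that on the signal of the lipid list, and those on the other housekeeping lists, were chosen after the results were seen. The replicate 1 list held 21 peaks on the mitochondrial chromosome, the highest at rank 29 of 30000, and the replicate 2 list held 0. These peaks enter no comparison. A further 2739 summits of the pooled list had the highest −log10 q that list gives and lay below the IDR cutoff, and 78.1% of them had a summit within 100 bp in both replicate lists. Of these, 51.9% lay within 1 kb of a TSS (95% Wilson interval 50.04 to 53.8%), against 64.8% of the IDR set.

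The summit with the highest signal, and 3 of the 6 highest, lay inside sug, the gene whose product was tagged. Carry-over of complementary DNA or of a coding plasmid would place signal in the coding exons, and 0 of the 5 summits lay there, which argues against it. Extra genomic copies of the locus in the transgene, which would raise signal over the carried region, stay open. The number of summits within 20 kb stood at the 88.1th percentile, under the bound of 90 set beforehand. It stood at 88.5 without replicate 1 and 86.7 without replicate 2. The 98.6 among the higher-signal summits counts the 5 inside the gene, which all have high signal, so it restates the pattern and decides nothing. The planned window of 100 kb gave 92.8, above 90, but the bound was set for 20 kb. The 6 summits around the gene had a median signal percentile of 70.4 with a range from 10.7 to 97.3. Binding of the factor to its own gene is 1 hypothesis beside copy number.

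Promoters held 64.8% of the summits, and general recovery of active promoters may account for part of that. Ribosomal protein genes, fixed as a control for active promoters, were bound 2.17 times as often as matched lists. Among other housekeeping lists, mitochondrial ribosomal proteins (2.37-fold) and the proteasome (1.72-fold) passed. Mitochondrial complex I (1.06-fold, permutation adjusted p = 0.856) and the vacuolar ATPase (1.21-fold, permutation adjusted p = 0.495) did not. The complex I list also holds unbound genes named as like forms of subunits, so its share is not that of the main complex alone. For the lipid list the median best signal of the bound genes stood at the 78.0th percentile of random lists of bound genes, between the bounds that would have separated the explanations. The control used by the authors was not analysed here, so an excess at lipid genes cannot be told apart from active promoters. No biological explanation was tested for the promoter preference as a whole.

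The GLIS word was concentrated at summits, and GC content together with promoter position was weighed as its source. At random positions matched on arm, GC and TSS distance, the word was 13.6-fold rarer than at summits (exact McNemar test, adjusted p = 6.85e-15). This argues against GC content and TSS distance as the whole source. The matching did not cover runs of C, which the word contains. Other words with such runs were also in excess, ACCCCCC at 3.52% of summits (3.03-fold over flanks) and GCCCCCC at 3.56% (3.33-fold). A preference for runs of C in general was therefore not excluded. Direct recognition of the word by the tagged factor is a hypothesis, and 68 of the 9342 summits (0.728%) carry this exact word within 100 bp.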

How the results depend on the processing

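Depth is unknown, and 1 replicate alone stands for each of the sets without the other. Of 386 values recomputed, 337 were counted as unchanged. These kept their direction and side of the threshold, changed direction without passing in either setting, or stayed within their spread. Among the unchanged were the promoter share (53.8 to 77.1% over all settings, always above relocated summits), the lipid and ribosomal protein lists and the GLIS and GATA words. Changes of direction counted this way include the Mef2 word (1.22-fold, but 0.656 at distal summits) and the hedgehog list (1.13-fold, but 0.614 with the higher-signal summits). Of 85 values for promoter summits of named genes, 81 kept their call. The stricter IDR score was not run, and the pooled list gave identical values, so neither is counted. Relocation within 50 kb, 1 summit per 500 bp for words, and distinct intervals were chosen after seeing the data. The cause of the changes below was not tested.

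Replicate agreement was 85.0% for overlap by 1 bp, 56.2% for overlap by 50% of both, 70.8% for the 1000 highest and 56.2% for all peaks. With the higher-signal summits only, the signal difference in promoter share was 2.60 points, the GLI word passed (2.50-fold), sug stood at 98.6 (92.8 with a 100 kb window on all summits), chromosome 4 at 0.220, the X at 0.875, the M1BP word at 3.93-fold, 3 lists were bound less often, and folds were 0.432 for epidermis and trachea, 0.628 for muscle, 1.13 for tRNA genes and 2.21 for sugar-responsive regulators, which passed.

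Leaving out each replicate gave a promoter share difference by signal of 4.52 to 13.3 points, 4 to 7 words in excess, GAGA at 1.08 to 1.41, CA repeat at 1.099 to 1.31, E-box at 1.13 to 1.33, epidermis and trachea at 0.289 to 0.407 (not passing without replicate 1), sugar-responsive regulators at 1.70 to 1.81 and tRNA genes at 1.18 to 1.60. Against matched positions Grainy head (1.94) and AP-1 (1.61) passed. Farther than 1 kb from a TSS 4 words passed, and GAGA (1.11), Zelda (0.597), DRE (1.33) and M1BP (1.20) did not. Within 50 bp 4 words passed in excess, GAGA turned to 0.932, and CA repeat (1.16) and E-box (1.13) did not pass. Within 200 bp, with flanks 1 kb away, the E-box was at 1.08.

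With a promoter of 500 bp sugar-responsive regulators passed (1.77), and with 2 kb epidermis and trachea did not (0.508), while receptors stood at 0.0520 and 0.198 and still passed. Random lists without matching gave 5 lists bound more often and 2 less often, with glycolysis (2.16) and sugar-responsive regulators (1.91) passing, and epidermis and trachea (0.365), neurons and glia (0.383) and muscle (0.638) not. Counting the gene body, sugar-responsive regulators passed (1.72) and tRNA genes did not (1.13). By summits per kb, 0 of the 6 genes with most summits stayed.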

Other observations

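All lists and comparisons here were chosen after the data were seen. Among further gene groups, mitochondrial ribosomal proteins were bound at 45 of 73 promoters (61.6%) against 19.0 in matched lists (2.37-fold, permutation adjusted p = 0.0004) and proteasome subunits at 21 of 32 against 12.2 (1.72-fold, permutation adjusted p = 0.003). Lists for other housekeeping complexes did not pass: mitochondrial complex I had 14 of 34 against 13.2 (permutation adjusted p = 0.856) and the vacuolar ATPase 14 of 29 against 11.6 (permutation adjusted p = 0.495). The complex I list holds ND-51L1, ND-51L2, ND-24L, ND-49L and ND-20L, named as like forms of subunits and all unbound. Its share is therefore not that of the main complex alone, though subunits such as ND-75 and ND-23 were also unbound. Cuticle proteins were bound at 5 of 95 promoters against 27.3 (0.183-fold, permutation adjusted p = 0.0004) and odorant binding proteins at 4 of 51 against 14.2 (0.282-fold, permutation adjusted p = 0.00187). The Jonah serine proteases had 7 of 16 against 3.54 (permutation adjusted p = 0.0845). The cuticle, odorant binding and Jonah lists hold neighbouring genes that were counted separately, so their p can be too small.

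Among bound genes, promoter signal was compared between lists. The median best signal was 1150 for the 11 bound glycolysis genes and 1139 for the 12 bound genes of carbohydrate digestion and transport, against about 517 and 520 for random lists of bound genes, and neither passed the correction over 15 lists (permutation adjusted p = 0.0502 for both). The GLIS word was found at 1.44% of the 1869 summits with the highest signal and 0.428% of the 1868 with the lowest (Fisher's exact test, adjusted p = 0.0107), while the M1BP word went the other way, at 0.696% and 2.03% (adjusted p = 0.00449). Of the 50 depleted words of 7 bases with the lowest p, 46 contained AGGA or TCCT, against 255 of all 8192 words by the same rule.

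Got2, P5CDh1 and Aldh7A1, among the highest peaks, encode enzymes with roles in amino acid breakdown, and a preference for that pathway was tested on a list without the genes of the 15 highest peaks. Of its 19 genes 15 were bound against 8.99 in matched lists (1.67-fold, permutation adjusted p = 0.008). Shmt, a serine hydroxymethyltransferase, had a signal of 3509, Oat, the ornithine aminotransferase, 2746 and Hn, the phenylalanine hydroxylase, 2085, while Tat, Hpd, Faa and hgo of tyrosine breakdown had no promoter summit. The highest promoter summits of Oat and of cn, also on the list, lay 991 and 897 bp from their TSSs, near the edge of the window. The list was not recomputed with other promoter windows. The pattern was noticed and tested in the same peak set, so it remains a hypothesis, and general recovery of active promoters (ribosomal protein genes at 2.17-fold) may also contribute.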
